A study of Rattus norvegicus with 20 samples.

How the data were processed

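Expression was measured on Affymetrix rat arrays in the central nucleus of the amygdala of 20 alcohol-preferring rats, 10 of them with access to ethanol at 15% and 30% in adolescence and 10 with water only. Per the labels' protocols, RNA was extracted with Trizol and an RNeasy column, and biotin-labelled cRNA was made with the 3' IVT Express kit. Per the submitters' processing notes the values were made with RMA (robust multi-array average), whose version is not given in the sources used here. The deposited values are log2 probe set summaries per array, as the authors made them. The log base was read from the values, which ran from 3.82 to 16.16 with array medians of 7.92 to 7.96. The scanner, the filters and the statistical test of the authors are not given in the sources used here.

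The table held 31099 probe sets with 0 missing values, of which 57 were controls. The annotation gave 1 gene symbol for 20826 probe sets, several for 436 and none for 9780 others. Gene names were checked by Entrez identifier against a reference gene table of assembly GRCr8, used for names and chromosomes, which held 20764 of those identifiers and changed 6 symbols. The symbols named 14217 genes.

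Groups were taken from the labels. The labels name no batch, and no animal number occurs in both groups, so no pairing was used. The accession order falls into 3 runs, each holding ethanol and water arrays in equal number. The first and the second run hold 4 arrays per group, and the last holds 2. These runs were treated as a candidate processing batch that no label names.

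The main choices were fixed before the data were examined: the comparisons, tests, thresholds, gene lists, the rule for named genes and most alternatives. Probe sets were kept where their mean over all arrays was above the 40th percentile of the non-control probe sets (log2 7.14), which left 18625. Of these, 13608 had 1 symbol, for 10159 genes. Ethanol minus water was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The median SE of a log2 difference was 0.0624, which sets the precision that 10 arrays per group give. Fold values in the text are 2 to the power of the difference of mean log2 values.

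Gene lists were written from textbook knowledge, 23 of functions and 12 of cell types or neighbouring regions. They were tested with limma's camera with a preset correlation between genes of 0.01, two-sided, adjusted over 35 lists, with 1 probe set per gene (the highest mean). Camera with an estimated correlation and limma's fry were run beside it. A list of blood markers had fewer than 5 measured members and was not tested. Within each list the members' limma p-values were also adjusted over the list alone. The score of a list is the mean of its members in an array, and its difference was tested by a two-sided permutation test of 100000 resamples. The distance between the mean profiles of the groups was tested one-sided in the same way. Spread was tested two-sided, as the median log2 ratio of variances of ethanol over water. Settings with fewer groupings were enumerated in full. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

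Named genes were probe sets with exactly 1 symbol. They were the genes past the threshold, up to 12 per direction, or up to 6 with the smallest p where fewer passed. From each list they were up to 4 members past the threshold, or else up to 2 with the smallest p. Crh, Npy, Bdnf, Penk, Pdyn, Prkcd, Sst and Gad1 were named whatever their result. Genes past the threshold adjusted over their list alone, the called probe sets without a symbol, and Fkbp5 and Tsc22d3 were chosen after their values were seen.

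Array quality was read from the correlation of each array with the others, the 3' to 5' signal ratio of control probe sets, and the hybridisation and poly-A controls. Arrays were taken to stand apart where their mean correlation was under 0.976, which is 3 scaled median absolute deviations below the median. These were ethanol animal 5 and water animals 15 and 18, and all were kept.

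The alternatives were no filter, a filter at the 60th percentile, centring arrays on their median, cyclic loess, array quality weights, eBayes with trend and robust settings, the run as a block, the 3' to 5' ratio as a covariate, the striatal and the cortical scores as covariates, and leaving out each animal in turn. For the count of genes an adjusted threshold of 0.10, an ordinary linear model and 1 probe set per gene were added, and for lists all probe sets of a gene. For the whole profile, each probe set was also divided by its SD. Leaving out the arrays that stand apart, the myelin score as a covariate and an adjusted threshold of 0.25 were chosen after seeing the data.

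The fit was tested on simulated data with the means and residual spread of these arrays, in which 200 probe sets were changed. Among 40 probe sets per size, 1 was called at a log2 change of 0.1, 11 at 0.2, 20 at 0.3, 36 at 0.5 and 39 at 1. Of 115 calls 8 were false. A list of 23 members shifted by -0.2 was called by camera (adjusted p = 2.18e-18; adjusted p = 2.62e-07 with an estimated correlation) and fry (adjusted p = 1.21e-09). With no change planted, limma called 0 probe sets (4.87% at an unadjusted p under 0.05), and camera and fry called 0 lists. Genes were simulated as independent, so these gene and list results hold for uncorrelated genes. Random splits of the real animals, given below, reached 418 called probe sets and 3184 at an unadjusted p under 0.05.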

Results

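Gene expression was measured in the central nucleus of the amygdala of alcohol-preferring (P) rats, a line bred for high voluntary alcohol intake. The nucleus is a mostly GABAergic output region of the amygdala that takes part in stress and alcohol responses. During adolescence 10 animals had access to ethanol solutions of 15% and 30%, and 10 animals had water only, with 1 array per animal. Each array gave log2 values for 31099 probe sets. The array medians lay between 7.92 and 7.96, and pairs of arrays correlated at 0.947 to 0.995. The number of arrays limits the precision of every value below.

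The comparison of ethanol with water asked which transcripts differ in this nucleus after adolescent drinking. Angptl4, which encodes a secreted inhibitor of lipoprotein lipase and lies on chromosome 7, was the named gene that passed the test over all probe sets. Its log2 value fell from 9.50 ± 0.099 to 9.22 ± 0.096 (SD, n = 10 per group), a log2 difference of -0.27 (SE 0.046), and the groups did not overlap. The largest difference among the called probe sets belonged to probe set 1381553_at, which has no gene symbol in the table used here. It was 2.15-fold lower with ethanol, at 7.27 ± 0.46 against 8.38 ± 0.26 (SD, n = 10 per group). Probe sets 1379708_at and 1379952_at, also without a symbol, rose by 0.28 (SE 0.044) and 0.43 (SE 0.069) on the log2 scale.

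**Figure D1:**
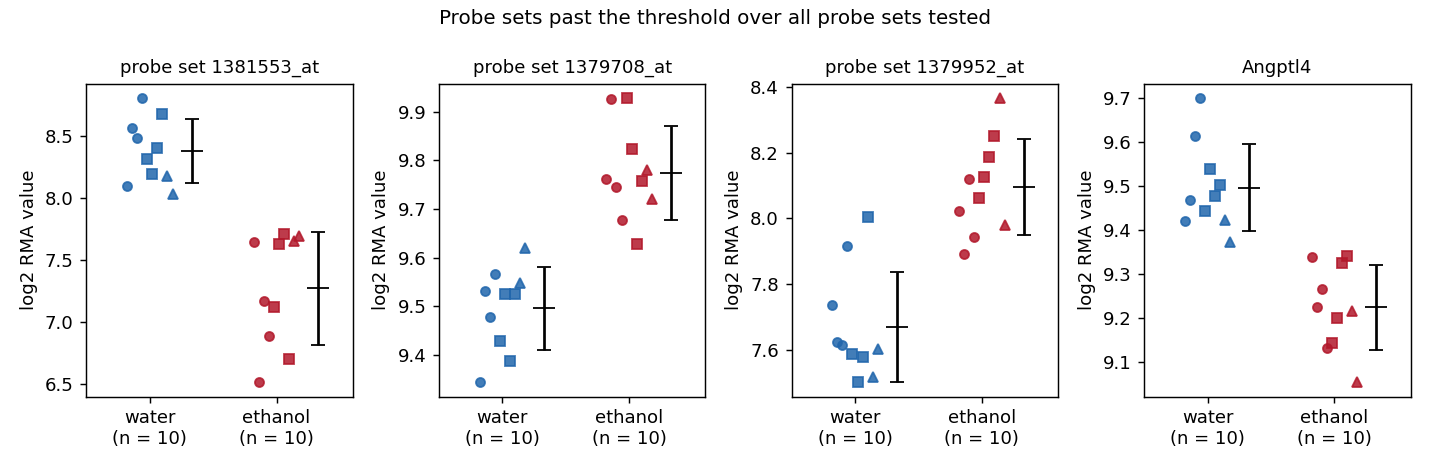
Log2 RMA values per animal for the 4 probe sets past the threshold, with water in blue and ethanol in red. Circles, squares and triangles are the first, second and last run of the accession order, and the black bar is the mean with its SD. Probe set 1381553_at and Angptl4 lie lower in every ethanol animal than in every water animal.

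These 4 probe sets, 2 higher and 2 lower, were those past limma's adjusted threshold of 0.05 among 18625 tested. Their limma adjusted p-values were 0.00799 for 1381553_at, 0.0212 for each of the probe sets that rose, and 0.0340 for Angptl4. For each of them 10 of 10 ethanol animals lay on the same side of the water mean. The differences of Angptl4 in the 3 runs of the accession order were -0.31, -0.24 and -0.26, and those of 1381553_at were -1.44, -1.11 and -0.43. The last run holds 2 animals per group, so here and below its sign alone decides little. At an unadjusted p under 0.05 there were 2393 probe sets, 12.8% of those tested, of which 1373 were higher and 1020 lower. The count of calls moved with single arrays. Leaving out water animal 14, 16, 17 or 18 or ethanol animal 6 left 1, leaving out ethanol animal 3 left 2, and leaving out water animal 20 gave 8. The Angptl4 call was lost without ethanol animal 2, 3, 4, 5, 6, 9 or 10 or water animal 14, 16, 17, 18 or 19, with limma adjusted p-values up to 0.104. Probe set 1379708_at was lost without ethanol animal 6 or water animal 14, 16, 17 or 18 (up to 0.0606), and 1379952_at without these or ethanol animal 3 (up to 0.0615). Array quality weights gave 23 calls, and limma called 0 with the myelin score as a covariate (2342 at an unadjusted p under 0.05) or with 1 probe set per gene (1278). With the myelin score the differences stayed near their size, at -1.03 (SE 0.17) for 1381553_at, 0.25 (SE 0.045) for 1379708_at, 0.41 (SE 0.075) for 1379952_at and -0.28 (SE 0.050) for Angptl4, each with a limma adjusted p of 0.0718. With 1 probe set per gene the probe sets without a symbol are not tested, and the adjusted p of Angptl4 was 0.0743.

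Other genes with the smallest p-values did not pass, and their values are given as measured. Pdk4, which encodes a kinase that holds back pyruvate oxidation, differed by -0.99 (SE 0.21), with -1.24, -1.28 and 0.12 in the 3 runs. C1r, a protease of the classical complement pathway, differed by -0.52 (SE 0.11), the fructose transporter Slc2a5 by -0.29 (SE 0.057), Adamts9, a matrix protease, by -0.42 (SE 0.090), and the transcriptional regulator Zhx2 by -0.23 (SE 0.045). On the higher side were Cwc25 at 0.37 (SE 0.079), the small GTPase Arf3 at 0.27 (SE 0.060), the mitochondrial carrier Slc25a23 at 0.26 (SE 0.059), the co-chaperone Bag4 at 0.20 (SE 0.042), Zfp292 at 0.19 (SE 0.043) and the lysosomal acetyltransferase Hgsnat at 0.17 (SE 0.040). The limma adjusted p-values of the lower genes were 0.140, and those of the higher genes ran from 0.140 to 0.174. For Zfp292 the other 5 probe sets gave -0.12 to 0.13, while the other probe sets of Slc25a23 (0.14), Arf3 (0.13) and Hgsnat (0.13) had the same sign. Genes fixed for report whatever their result were also not called. Their differences were 0.03 for the stress peptide Crh (SE 0.35), -0.08 for Npy (SE 0.14), 0.01 for Bdnf (SE 0.44), 0.10 for Penk (SE 0.13), 0.06 for Pdyn (SE 0.19), 0.16 for Prkcd (SE 0.19), 0.14 for Sst (SE 0.18) and 0.05 for Gad1 (SE 0.044), with limma adjusted p-values of 0.616 to 0.998. Without ethanol animal 1 Penk was at 0.23 (limma adjusted p = 0.138), and without water animal 18 Gad1 was at 0.02. Prkcd was at 0.05 without water animal 13 and between 0.09 and 0.10 without water animal 16 or ethanol animal 2, 6 or 7, and Sst was at 0.03 without water animal 16, 0.09 without ethanol animal 6 and 0.08 without ethanol animal 7. The differences of Crh, Npy, Bdnf and Pdyn changed sign when single animals were left out.

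Genes that glucocorticoids induce were lower as a group with ethanol. The mean of the 23 measured members was 9.96 ± 0.11 in ethanol and 10.16 ± 0.10 in water animals (SD, n = 10 per group), and 10 of 10 ethanol animals lay below the water mean. Adjusted over the list alone 11 members fell and 1 rose, against 1 adjusted over all probe sets. Without ethanol animal 1 the members that fell numbered 7, and with the astrocyte, choroid plexus or pan-neuronal score as a covariate 6. The members that fell included Pdk4, the cell cycle inhibitor Cdkn1a (-0.64, SE 0.16), the kinase Sgk1 (-0.55, SE 0.15), the thioredoxin inhibitor Txnip (-0.50, SE 0.16) and the metallothionein Mt2A (-0.41, SE 0.15). Sult1a1 (-0.30), Nfil3 (-0.29), Angptl4 (-0.27), Cebpb (-0.25), Errfi1 (-0.24) and Cebpd (-0.14, and -0.07 in its other probe set) fell too, and the phosphatase Dusp1 rose by 0.47 (SE 0.15). Fkbp5 and Tsc22d3, which are common readouts of the glucocorticoid receptor, differed by 0.05 (SE 0.10) and -0.02 (SE 0.072). In the last run Pdk4 (0.12), Sgk1 (0.09), Txnip (0.04) and Cebpd (0.17) had the opposite sign. With the myelin score as a covariate, a setting chosen after seeing the data, Pdk4 was at -0.63, Sgk1 at -0.29 and Txnip at -0.24, and with the dissection scores Dusp1 was at 0.31.

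The shift of this list passed camera (adjusted p = 1.05e-08), fry (adjusted p = 0.00583) and a two-sided permutation test of the list score (p = 0.00046, adjusted over 35 lists 0.0161). With an estimated correlation in place of the preset camera did not call it, with adjusted p = 0.0613 with an estimated correlation. With the run as a block that value was 0.0270, and it was 0.0431 with no filter, 0.0416 with median centring and 0.0382 with the dissection scores. It was also under 0.05 without ethanol animal 7 (0.0216) or 10 (0.0435) or water animal 13 (0.0489), 18 (0.0380) or 21 (0.0375). It went up to 0.204 without ethanol animal 1, 0.160, 0.138 and 0.121 without water animals 20, 19 and 15, and 0.224 with array quality weights. The score differences in the 3 runs were -0.26, -0.24 and -0.03, and permutation within runs gave p = 0.00034. Without the 3 arrays that correlated least with the others, a setting chosen after seeing the data, the difference was -0.19 (exact permutation p = 0.00148). The myelin score moved with the group in the same direction, by -0.36.

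**Figure D2:**
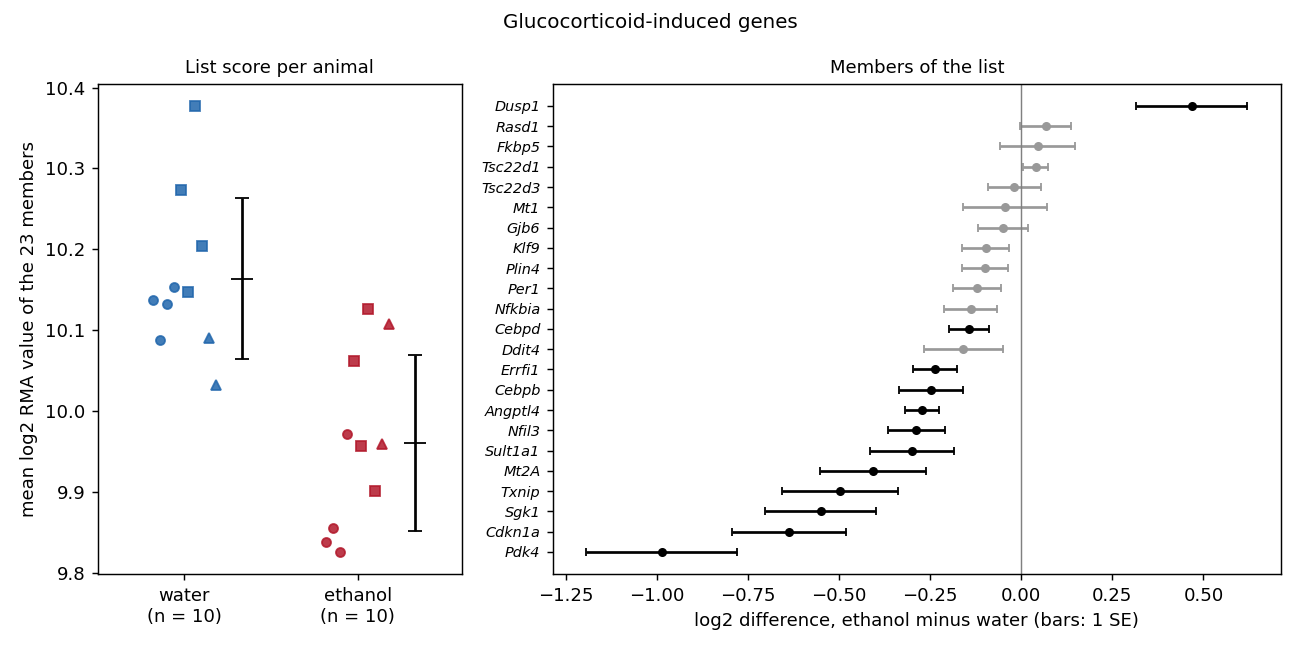
Left, the mean log2 RMA value of the 23 measured glucocorticoid-induced genes per animal, with the group mean and SD as black bars and symbols for the 3 runs of the accession order. Right, the log2 difference of each member with its SE, in black where it passed adjusted over the list alone. Pdk4 has the lowest value (-0.99) and Dusp1 the highest (0.47).

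Of the 35 gene lists tested, 20 passed camera with its preset correlation of 0.01, 6 higher and 14 lower. Random splits of the animals gave a median of 11 such calls and up to 22. With an estimated correlation camera called 0 (4 at an unadjusted p under 0.05), and fry called 2, the glucocorticoid-induced list and the monoamine and acetylcholine receptor list. In the permutation test of list scores the glucocorticoid-induced list passed. Apart from Angptl4 in that list, no tested member of any list passed limma's adjustment over all probe sets. Adjustment over a list alone does not correct for the number of lists. Leaving out water animal 18 left 12 camera calls, and with the myelin score as a covariate 8 were called. Kept with the myelin score were the glucocorticoid-induced, choroid plexus, pan-neuronal, oligodendrocyte precursor and matrix lists. Gained were the immediate early, central amygdala neuropeptide and oxidative phosphorylation lists. Single animals also ended calls of lists with the larger adjusted p-values. Without water animal 18 the camera adjusted p was 0.321 for GABA signalling, 0.293 for oxidative stress defence, 0.293 for the unfolded protein response, 0.227 for glutamate receptors, 0.130 for interferon response and 0.0811 for alcohol and aldehyde metabolism. GABA signalling was also lost without ethanol animal 4, 6, 8, 9 or 10 or water animal 12, 16 or 17, and oxidative stress defence without ethanol animal 2, 3, 4, 6, 8 or 10 or water animal 14, 16, 17 or 19. The unfolded protein response was lost without ethanol animal 2, 4, 6 or 10 or water animal 17, and glutamate receptors without ethanol animal 3 or 10 or water animal 17. Cholesterol synthesis was lost without ethanol animal 2, 3 or 5 or water animal 17 or 18 (up to 0.192), and ribosomal proteins without ethanol animal 8 or water animal 14, 17 or 18 (up to 0.116). Leaving out water animal 18 also moved list means, from 0.056 to 0.026 for GABA signalling, 0.070 to 0.041 for glutamate receptors, -0.067 to -0.025 for interferon response and -0.075 to -0.044 for alcohol and aldehyde metabolism. The mean went from -0.057 to -0.025 for oxidative stress defence and -0.035 to -0.014 for the unfolded protein response. For Toll-like receptor signalling it went from -0.061 to -0.038, for synaptic vesicle release 0.076 to 0.050 and for ribosomal proteins -0.017 to -0.0095.

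Oligodendrocyte and myelin markers were lower by camera (adjusted p = 2.05e-09; adjusted p = 0.517 with an estimated correlation). All 24 measured members had a lower mean with ethanol, with a median difference of -0.35, and none passed adjusted over the list alone. Examples were the myelin-associated Mag (-0.48, SE 0.21), Bcas1 (-0.45, SE 0.18) and the transcription factor Sox10 (-0.34, SE 0.14). The myelin score was 11.60 ± 0.45 in ethanol and 11.96 ± 0.42 in water animals (permutation p = 0.0831). It differed by -0.32 and -0.77 in the first and second run and by 0.39 in the last. Oligodendrocyte precursor markers had 12 of 13 members lower, with Fyn at -0.18 (SE 0.057) and -0.0022 in its other probe set (camera adjusted p = 2.94e-05; adjusted p = 0.409 with an estimated correlation), and their last run also differed in sign (0.16).

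Camera with its preset also called the matrix, meningeal, choroid plexus and astrocyte lists lower, and fry did not (adjusted p = 0.125, 0.410, 0.295 and 0.286). With the myelin score as a covariate camera lost the meningeal (mean -0.16, adjusted p = 0.117) and astrocyte (-0.034, adjusted p = 0.142) lists. It kept the matrix (-0.059, adjusted p = 0.0201) and choroid plexus (-0.84, adjusted p = 0.00303) lists. In the perineuronal net and extracellular matrix list 23 of 25 members had the lower sign (camera adjusted p = 2.94e-05; adjusted p = 0.348 with an estimated correlation), and the metalloproteinase inhibitor Timp1 fell by 0.43 (SE 0.10) when adjusted over the list alone. All 17 meningeal and fibroblast markers had the lower sign (camera adjusted p = 0.000241; adjusted p = 0.589 with an estimated correlation), with the collagen gene Col1a2 at -0.57 (SE 0.28) and Ogn at -0.70 (SE 0.39). Without water animal 18 these were -0.36 and -0.40, and the meningeal list mean was -0.21 in place of -0.41. All 9 choroid plexus and ependyma markers did too (camera adjusted p = 0.000619; adjusted p = 0.517 with an estimated correlation). Ttr, the transthyretin gene of choroid plexus, differed by -2.81 (SE 1.40), Tmem212 by -1.08 (SE 0.40) and Foxj1 by -0.54 (SE 0.24). Of the astrocyte markers 16 of 21 had the lower sign (camera adjusted p = 0.00192; adjusted p = 0.517 with an estimated correlation), with the filament gene Gfap at -0.51 (SE 0.17) and Aldh1l1 at -0.28 (SE 0.096), and none of them passed adjusted over the list alone. The Gfap differences were -0.80, -0.56 and 0.18 in the 3 runs, and the astrocyte score was at 0.0087 in the last.

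Of the lists of neuronal genes camera called 6 higher, each of them lost with an estimated correlation, and the others were not called. The ion channel list had 37 of 43 members higher (camera adjusted p = 3.43e-05; adjusted p = 0.409 with an estimated correlation; permutation p = 0.00667, adjusted 0.117). Its score lay above the water mean in 10 of 10 ethanol animals. Scn2a, a sodium channel gene, rose by 0.23 (SE 0.057) adjusted over the list alone, with -0.04 in the last run, and Kcnd3, a potassium channel gene, was at 0.24 (SE 0.071). Pan-neuronal markers were higher in 23 of 24 members (camera adjusted p = 0.000147; adjusted p = 0.517 with an estimated correlation), and synaptic vesicle release genes in 28 of 31 (camera adjusted p = 0.00208; adjusted p = 0.573 with an estimated correlation). In that list the membrane fusion genes Nsf (0.18, SE 0.050) and Snap25 (0.14, SE 0.042) rose adjusted over the list alone. Glutamate receptor genes (camera adjusted p = 0.0217; adjusted p = 0.597 with an estimated correlation) included the metabotropic receptor Grm7, which rose by 0.45 (SE 0.11) adjusted over the list alone. The glutamate score was at -0.02 in the last run. With the myelin score as a covariate the glutamate list mean went from 0.070 to 0.011 (camera adjusted p = 0.647). GABA signalling genes (camera adjusted p = 0.0459; adjusted p = 0.589 with an estimated correlation) included Gphn, the scaffold of inhibitory synapses. Gphn rose by 0.14 (SE 0.036) adjusted over the list alone (limma adjusted p = 0.230 over all probe sets). Striatal medium spiny neuron markers were higher in 25 of 26 members (camera adjusted p = 0.00247; adjusted p = 0.589 with an estimated correlation). None passed adjusted over the list alone, and Rasgrp2 was at 0.21 (SE 0.079) and 0.01 in its other probe set. Without ethanol animal 1 the striatal list mean was 0.24 in place of 0.16.

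**Figure D3:**
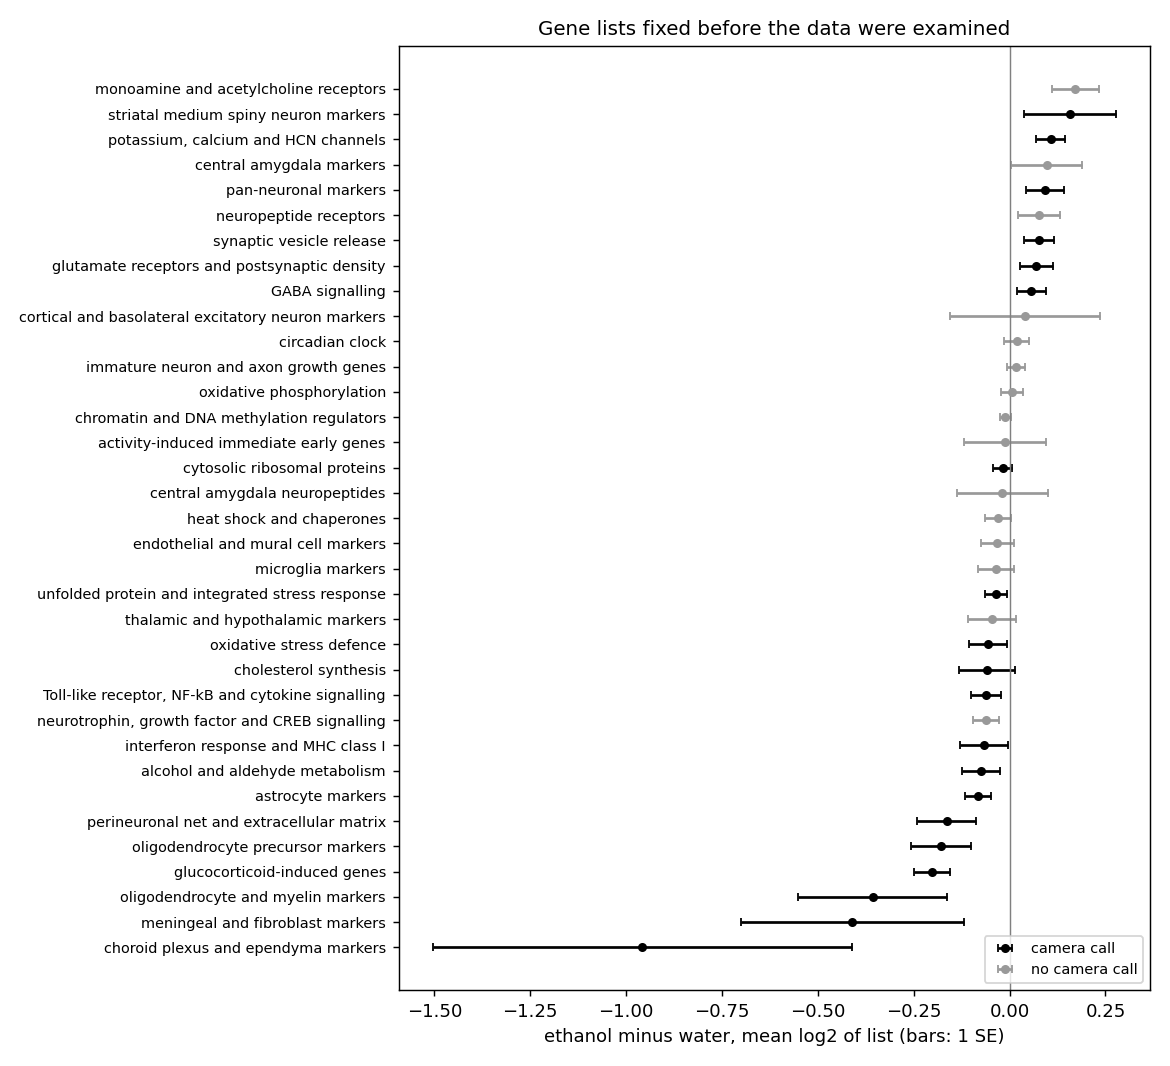
Difference of the mean list score between ethanol and water animals, in log2, for the 35 gene lists, with bars of 1 SE between animals. Black points are lists called by camera with its preset correlation. The glucocorticoid-induced list is at -0.20, and the choroid plexus and ependyma list, with the widest bar, is at -0.96.

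Among lists of metabolism, immunity and stress, camera called the alcohol and aldehyde metabolism list lower (adjusted p = 0.0174; adjusted p = 0.589 with an estimated correlation), and the acetyl-CoA synthetase gene Acss1 fell by 0.21 (SE 0.057) adjusted over the list alone, while the list score was at 0.03 in the last run. With the myelin score as a covariate the mean of this list went from -0.075 to -0.0048 (camera adjusted p = 0.667). The Toll-like receptor, NF-kB and cytokine list was lower in 17 of 22 members (camera adjusted p = 0.0159; adjusted p = 0.477 with an estimated correlation), while Tnfaip3, an inhibitor of NF-kB, rose by 0.21 (SE 0.052) adjusted over the list alone. The interferon response and MHC class I list (camera adjusted p = 0.0153; adjusted p = 0.60 with an estimated correlation) had Psmb9 at -0.36 (SE 0.14). Cholesterol synthesis (0.0221; adjusted p = 0.618 with an estimated correlation), with Cyp51 at -0.15 (SE 0.067), unfolded protein response (0.0361; adjusted p = 0.60 with an estimated correlation), with Pdia4 at -0.14 (SE 0.052), oxidative stress defence (0.0477; adjusted p = 0.60 with an estimated correlation), with Gstm5 at -0.19 (SE 0.065), and cytosolic ribosomal protein lists (0.0153; adjusted p = 0.618 with an estimated correlation), with Rpl22 at -0.10 (SE 0.041), were each called lower by camera at the adjusted p given first. No member of these 4 lists passed adjusted over its list alone, and the last run had the opposite sign for each (0.10, 0.01, 0.02 and 0.0047). With 2 animals per group in that run, these values do not settle a sign.

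The other 15 lists were not called by camera in the main test. The circadian clock list (adjusted p = 0.644) had members in both directions, which a directional test such as camera cannot detect. Fry's mixed test, which ignores direction, did not call it either (adjusted p = 0.065). Adjusted over the list alone Nfil3 fell and the clock output gene Dbp (0.22, SE 0.066) and Nr1d2 (0.14, SE 0.043) rose. Immediate early genes (adjusted p = 0.528) had Ier2 higher by 0.34 (SE 0.092) and the transcription factor Crem lower (-0.24, SE 0.066), both passing adjusted over the list alone. With the myelin score as a covariate the immediate early list was called lower, at a mean of -0.11 (camera adjusted p = 0.0117). Monoamine and acetylcholine receptors (camera adjusted p = 0.0695, fry adjusted p = 0.0199) were at a mean of 0.17, with the adrenergic receptor Adra2c at 0.52 (SE 0.16). Their fry call was lost with no filter, the dissection scores or the myelin score, and without ethanol animal 4 or water animal 14 or 20. Neuropeptide receptors (adjusted p = 0.208) had Npy5r at 0.35 (SE 0.12) and Npy1r at 0.25 (SE 0.086). Of the 18 central amygdala neuropeptides (adjusted p = 0.693), 9 were higher and 9 lower. With the myelin score they too were called lower, at a mean of -0.15 (camera adjusted p = 0.0431). The adjusted p-values by camera were 0.0695 for endothelial, 0.0861 for microglia, 0.155 for central amygdala, 0.311 for thalamic and hypothalamic and 0.311 for cortical and basolateral markers. They were 0.662 for chromatin regulators, 0.716 for neurotrophin and CREB signalling, 0.873 for immature neuron genes, 0.873 for oxidative phosphorylation and 0.956 for heat shock genes. In the neuropeptide, neurotrophin and heat shock lists the mean and median differed in sign.

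The distance between the whole profiles of the groups was 17.2 log2 units, against a median of 12.5 in permuted groups (one-sided permutation p = 0.0474). The permutation p was 0.0704 without the filter on low values, 0.0509 within runs and 0.0604 without the 3 arrays that stand apart. With each probe set divided by its SD it was 0.0313. Spread between animals did not differ detectably. The median SD was 0.131 in ethanol and 0.145 in water animals, with a median log2 variance ratio of -0.24 (two-sided permutation p = 0.569). The RNA quality measure, the log2 ratio of 3' to 5' control signal, was 1.37 ± 0.18 in ethanol and 1.48 ± 0.21 in water animals (permutation p = 0.248). It differed between the 3 runs, with means of 1.6, 1.34 and 1.24 (permutation p = 0.00056, adjusted over 8 measures 0.00448).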

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

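Chosen only after the results were seen were the tests of RNA quality, accession run and marker scores on the glucocorticoid-induced list, and the tests of tissue share and animal variation on the myelin, channel and pan-neuronal lists.

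Some animals lay far from the rest of their group. The values below are the gap to the nearest animal divided by the range of the group. Of 282 groups tested 27 passed the critical value, or 9.57%, where chance gives about 1 in 20, and groups that share an array are not independent. Water animal 18 accounted for 10, ethanol animals 1 and 5 for 6 each, water animal 15 for 3, and ethanol animal 10 and water animal 17 for 1 each.

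Water animal 18 was highest for C1r (0.663), Cdkn1a (0.594), Sult1a1 (0.628), Foxj1 (0.488) and the interferon response list (0.500). It was lowest for Prkar2b (0.550) and the GABA signalling (0.645), pan-neuronal (0.482), channel (0.520) and synaptic vesicle (0.524) lists. Within the ethanol group animal 5 was highest for Cdkn1a (0.535), Hspb1 (0.473), Foxj1 (0.467), Ogn (0.654) and the choroid plexus (0.665) and meningeal (0.597) lists. Water animal 18 scored higher still on the choroid plexus (11.39 against 11.07) and meningeal (10.69 against 9.75) lists. Water animal 16 was at 10.45 and 9.70, so the gap rule did not flag water animal 18 there. Ethanol animal 1 was lowest for the enkephalin gene Penk (0.710), Dusp1 (0.508) and the immediate early (0.694), circadian (0.483) and striatal (0.480) lists, and highest for cholesterol synthesis (0.492). Water animal 15 was lowest for Grm7 (0.559) and the ATP synthase gene Atp5f1a (0.548) and highest for the hybridisation controls (0.523). Ethanol animal 10 was highest for Slc2a5 (0.855), and water animal 17 lowest for Tmem212 (0.614). For Slc2a5 the other ethanol animals lay close together, between 8.33 and 8.36. Ethanol animal 10, at 8.56, lay within the water range of 8.30 to 8.83.

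Lower expression of glucocorticoid-induced genes with ethanol was weighed against 3 technical explanations. With the 3' to 5' ratio as a covariate the list mean was -0.22, which argues against RNA quality. With each of the 12 marker scores as a covariate the largest fry p was 0.00258, for astrocyte markers, which argues against any 1 of those cell types as the whole cause. Permuting within the runs of the accession order gave p = 0.00034, but each run holds both groups in equal number, so an offset between runs cancels by design and this p is no evidence for or against a batch. Drinking in adolescence stays open as a hypothesis, as do a batch within runs and untested differences in handling, time of day or stress between the groups.

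Lower myelin with higher channel and pan-neuronal expression may reflect the share of white matter in the tissue taken. Differences predicted from the within-group slope on the myelin score correlated with those measured at r = 0.370 over 18591 probe sets. Predicted and measured differences come from the same arrays, and r was not compared with random splits of the animals. Groups that differ in myelin score by variation between animals alone could also give a positive r. This r therefore cannot decide whether white matter share is a cause. For the pan-neuronal list the within-group slope on the myelin score predicts a part of -0.0039 (SE 0.022) of a difference of 0.093 (SE 0.049). That difference did not itself pass (permutation p = 0.075, adjusted over all lists 0.298). Water animal 18 had the highest myelin score (12.60) and the lowest pan-neuronal score (12.20), while ethanol animal 1 was high in both (12.22 and 12.72). The slope pools such opposite patterns, so it cannot decide whether myelin share is a cause for this list. The criterion of the predicted part replaced an earlier one after the results were seen. The earlier one, on the value with the score as a covariate (0.097, SE 0.055, p = 0.0969, camera adjusted p = 0.00513), gave no verdict for either list. For the channel list the slope predicts 0.044 (SE 0.013) of 0.11 (SE 0.038). That difference had passed camera but not the permutation test adjusted over all lists (0.117). The remaining 0.064 (SE 0.033, linear model p = 0.0700, camera adjusted p = 0.0615) no longer passed camera. Water animal 18 also had the lowest channel score (9.72), and how far this slope rests on it was not tested. For this list myelin share and an effect of ethanol cannot be told apart. The myelin score difference itself (permutation p = 0.0831) is of a size that variation between animals could give.

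Few calls stood beside an excess of small p-values. Of 100 splits of the 20 animals, 2 gave as many called probe sets, the real 1 included. The real split called 4 and the highest other 418, and the real split called 1 when any 1 of 5 animals was left out. With 100 splits such a share is known only roughly, so chance is not firmly excluded. Why 1 other split gave 418 calls was not tested. For probe sets at an unadjusted p under 0.05 the count was 4 of 100, with 2393 in the real split and 3184 in the highest other. That share lies so near 0.05 that 100 splits cannot exclude chance. The whole-profile permutation p of 0.0474 was 0.0509 within runs, 0.0704 with no filter, 0.0604 without the arrays that stand apart and 0.0313 with each probe set divided by its SD. For lists called by camera it was 11 of 100, so chance cannot be excluded, with 20 in the real split and 22 in the highest other.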

How the results depend on the processing

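Chosen only after the results were seen were the tests without the arrays that stand apart, with the myelin score and at an adjusted threshold of 0.25. No paired analysis was possible because the groups share no animal numbers. The cause of the changes below was not tested, except where fewer animals or a looser threshold make it plain.

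The count of 4 called probe sets was 2 with the filter at the 60th percentile, where fewer probe sets were tested, 23 with array quality weights, 1 with the dissection scores, 0 by limma with the myelin score (2342 at an unadjusted p under 0.05), 0 with 1 probe set per gene (1278) and 230 at an adjusted threshold of 0.25. It ran from 1 to 8 when single animals were left out. Without the arrays that stand apart it was 4, with 2 shared. Probe set 1381553_at was past the threshold in 30 of 31 settings, 1379708_at in 24 of 32, 1379952_at in 23 of 31 and Angptl4 in 15 of 32, with adjusted p-values of Angptl4 from 0.0158 to 0.146. Over these settings the differences ran from -1.15 to -1.02, 0.25 to 0.29, 0.40 to 0.46 and -0.29 to -0.24, so the lost calls came with folds of about the same size.

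The count of 20 lists was 0 by camera with an estimated correlation (4 at an unadjusted p under 0.05), 2 by fry, of which 1 was shared, and 8 with the myelin score, of which 5 were shared. It ran from 12 to 23 when single animals were left out. The glucocorticoid-induced list passed camera in 32 of 32 settings, with fry adjusted p from 0.00123 to 0.0384 and adjusted p from 0.0216 to 0.224 with an estimated correlation. The cholesterol synthesis mean reversed to 0.0046 with the dissection scores and 0.052 with the myelin score, and the oxidative stress mean to 0.0081 with the myelin score.

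The whole-profile permutation p of 0.0474 was 0.0704 with no filter, 0.0509 within runs, 0.0604 without the arrays that stand apart and 0.0313 with each probe set divided by its SD. The spread ratio of -0.24 reversed to 0.17 without those arrays, to 0.0077 without water animal 15 and to 0.022 without water animal 18, and ran from -0.44 to 0.022 over single animals. Signal over background limits the low probe sets, which the filter left out.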

Other observations

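Chosen only after the result was seen were the tests of meningeal and choroid plexus signal on the complement list. The tests of 3 further gene lists were chosen before their result was seen, but after the glucocorticoid-induced genes and C1r had been seen. Their permutation p-values were adjusted over these 3 lists.

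Complement and acute phase genes had a lower mean with ethanol without passing as a group. With C1r and C1s left out the mean of 10 members was -0.25, and 9 of 10 ethanol animals lay below the water mean (permutation p = 0.0726, adjusted 0.0726). Adjusted over the list alone the complement inhibitor Serping1 (-0.63, SE 0.20) and the copper carrier Cp (-0.59, SE 0.20) fell, and A2m was at -0.90 (SE 0.35). Without water animal 18, whose C1r value also stood far from its group, the list mean was -0.16. The within-group slope on the meningeal score predicts -0.17 (SE 0.022) of the difference and that on the choroid plexus score -0.16 (SE 0.041), leaving -0.085 (SE 0.070, p = 0.246) and -0.087 (SE 0.11, p = 0.432). The pan-neuronal (-0.16, SE 0.048), myelin (-0.14, SE 0.050) and astrocyte (-0.13, SE 0.071) scores also predict over 50% of it, so the values do not single out 1 tissue. The makeup of the tissue taken, with meninges and choroid plexus among its parts, is a candidate explanation for most of it, and whether these genes shift apart from that stays undecided.

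A list of 32 targets of PPAR and FoxO factors, which mixes genes of lipid oxidation with other fasting genes, did not pass after adjustment. Its mean was -0.072 (permutation p = 0.0409, adjusted 0.0614), with 25 members of lower sign and 7 of higher. Adjusted over the list alone 4 fell, the carnitine acyltransferase Cpt1a (-0.17, SE 0.049), the thioesterase Acot1 (-0.31, SE 0.096), Pik3ip1 (-0.15, SE 0.049) and Klf15 (-0.16, SE 0.051). The value of Cat had been seen before. Sod2 and Gabarapl1 of this list, Glul of the list below and Vtn of the complement list also belong to lists fixed earlier, so their values were already computed.

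A second list of glucocorticoid receptor targets, with no gene of the first, had a mean of -0.070 over 27 members (permutation p = 0.0401, adjusted 0.0614), with 19 lower. At an unadjusted p under 0.05 there were 7 lower and 1 higher, and adjusted over the list alone 0 by limma. Rhoj and Spsb1 were left out of it because their values had been seen. Lower receptor activity and a weaker fasting-type response are both candidate explanations of the first list. Against lower receptor activity, the common readouts Fkbp5 (0.05, SE 0.10) and Tsc22d3 (-0.02, SE 0.072) did not pass as lower. The target Dusp1 rose by 0.47 (SE 0.15) adjusted over the first list alone. Dusp1 also belongs to the immediate early list, where it did not pass, and its limma adjusted p over all probe sets was 0.284. Lower receptor activity therefore stays open. Each explanation met the unadjusted criterion set for it and neither passed after adjustment. The second list and the fasting list share Klf15, Irs2, Sesn1 and Bcl6, so they are not independent.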
